A study of Mus musculus with 6 samples.

How the data were processed

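Dorsal root ganglia of 3 WT and 3 dt27J mice at postnatal day 4 were flash frozen after dissection, and total RNA was isolated and 300 ng of it labelled with Cy3, per the labels' protocols. Each sample was hybridised to 1 single-colour Agilent whole-genome array. The design text speaks of 3 animals per genotype, so each array is a separate animal. The genotype and the replicate number were taken from the sample labels. The labels also carry a date, which splits the arrays into 4 of the first date (2 per genotype) and 2 of the second (1 per genotype). The slide of each array, per the file headers, follows the date exactly, so a slide block equals the date block and was not run on its own. The sources used here do not say whether a date is a litter, and they state only that 2 litters were used.

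Per the file headers and the submitters' processing notes, the deposited scanner files were made with Agilent Feature Extraction 10.5.1.1, which subtracted the background and removed spatial trends within each array. The deposited processed signal is an intensity on a linear scale, not normalized between arrays. The deposited raw values are the median pixel intensity of a spot and of its local background. The authors' deposited series table holds log2 values, which were found by comparison with the scanner files to be centred on each probe's median over the 6 arrays, with column medians between -0.0041 and 0.0053. Over 8114 probes with a signal above 500 the authors' values rose with the centred scanner log2 values with slopes between 0.94 and 0.99, and over all tested probes with slopes between 0.71 and 0.76, so their scale is log2 and a higher value is a higher signal. What normalization and background correction the authors applied between the scanner files and this table is not given in the sources used here.

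The main values were log2 of the processed signal minus the array's 75th percentile of it. That percentile lay at a signal between 369.5 and 580. Control spots were left out, and so were spots that the scanner software called outliers. The remaining spots of a probe were averaged, since 245 probes are spotted 10 times each. This left 41086 of 41174 probes with a value on all 6 arrays, the other 88 being lost to outlier calls. A probe was tested if it was well above background on all 3 arrays of at least 1 genotype, which held for 26248 probes, and 24242 probes were well above background on all 6 arrays. No probe was saturated. A probe that was well above background on no array of a genotype has only a bound there. Its fold is given as at least the difference between the mean of the brighter genotype and the mean, over the dimmer arrays, of the higher of the probe's own value and the lowest value of any probe well above background on that array.

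The scanner files give accessions and no gene names. Probes were named by matching the accession, without its version, to the transcripts of a RefSeq gene table of assembly GRCm38.p6. The array's own annotation is from build mm9, so the table served only for names and for which genes neighbour each other, and no coordinates are given. A name was found for 24844 of 41174 probes and for 19381 of 26248 tested probes (73.8%), which stand for 13675 symbols. The other 6867 tested probes are unnamed here and entered the tests.

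Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0, on all 6 arrays with genotype and date as terms, and p values were adjusted by the Benjamini-Hochberg method over all tested probes with a threshold of 0.05. The genotype is balanced over the dates, so the date term does not alter a fold change and alters only its error. The date effect came from the same fit. Whether the genotype effect differs between dates was tested as an interaction term in a second fit, and the genotype difference within each date is given as a value. Fold changes are dt27J minus WT on the log2 scale, and errors are the standard errors of the moderated fit unless an SD is named. The number of arrays limits the precision, with 3 residual degrees of freedom and 3.74 added by the prior.

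The design, the tests, the gene lists, the rule for named genes and the alternatives listed below were fixed before the data were examined. The rule names every Dst probe and the 12 symbols with the largest rise and the 12 with the largest fall among those past the threshold, by the brightest probe past the threshold, in which every dt27J array lies on the same side of every WT array of its own date; clone-like names were left out. In each list the 3 members with the smallest p may be named. Every measured member may be named of the PERK-ATF4 arm of the unfolded protein response, ER chaperones, intermediate filaments, the plakins and the sex-linked genes, and in lists of erythroid cells and other tissues also the brightest member. Genes named outside this rule are said to be chosen after their values were seen.

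The 34 lists covered stress pathways (the PERK-ATF4 arm, ER chaperones and ER-associated degradation, heat shock, apoptosis, autophagy and lysosome, interferon response, immediate early genes, nerve injury and regeneration), cell structure and function (calcium handling, microtubules and motors, intermediate filaments, plakins and their partners, Golgi and vesicle transport, cholesterol synthesis, oxidative phosphorylation, cell cycle, voltage-gated channels), cells of the ganglion (proprioceptors, peptidergic and non-peptidergic nociceptors, low-threshold mechanoreceptors, pan-neuronal genes, satellite glia, myelinating Schwann cells, macrophages, blood vessels, fibroblasts and meninges) and cells or properties of other origin (erythroid cells, spinal cord, skeletal muscle, cartilage and bone, adipocytes, Hox genes, sex-linked genes). Each gene entered with its brightest tested probe, and 33 lists had at least 5 measured members. They were tested with limma's camera at a preset correlation between genes of 0.01, with the same test at an estimated correlation and with fry beside it, and p values were adjusted over the lists.

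The alternatives were no date block, the replicate number as a block, quantile normalization, normexp background correction with an offset of 50, the authors' values, no filter on dim probes, a filter on all 6 arrays, leaving out saturated probes, a trended and robust prior, array weights, other thresholds, 1 value per symbol, the first date alone, and leaving out each array in turn. Alternatives added after the data were seen are named with the results they bear on. The scanner files have no column of mean spot signals, so normexp was run on the median signals. Sex was read from Xist and the Y-linked probes. Extra lists of central nervous system, skeletal muscle and sympathetic neuron genes, which share no gene with the fixed lists, were written before their values were examined. Intervals of list medians come from 10000 bootstrap draws of the genes, and random lists matched on signal were drawn 10000 times. After the values were seen, the conditions for arguing against an explanation were tightened, to ask for an interval, for more than 1 array, for both dates and for probes chosen without WT 3, and 5 explanations that had been argued against became open. Sex as the only cause was tested by differences within each sex.

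The code was tested on simulated data for the 26248 probes, with the measured probe means and date differences and errors drawn from limma's fitted variance prior, 200 of them changed. The genotype test recovered 0% of changes of 1 on the log2 scale, 81% of changes of 2 and 94.5% of changes of 3, with 1.82% and 5.03% of the calls false at the larger sizes. With no change built in, the interaction test called 0 probes and the list tests 0 of 33 lists, and a blood vessel list moved by 0.7 was found (adjusted p = 1.23e-09). Only 200 probes were changed, where 7270 measured probes had an unadjusted p under 0.05 for genotype. The adjusted threshold was therefore harder to pass in the simulation, and its rates do not carry over to the measured data. The errors were drawn independently for each gene. In the measured data the estimated correlation was 0.24 for the vessel list and 0.82 for the skeletal muscle list. These runs therefore do not test lists whose genes move together.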

Results

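Gene expression was measured in dorsal root ganglia, the clusters of sensory neurons and their glia beside the spinal cord, taken from mice at postnatal day 4. The dt27J mouse carries a mutant allele of Dst, the gene for dystonin, a giant linker protein of the cytoskeleton whose loss causes a sensory neuropathy in the mouse. The series describes this age as before the phenotype, so the question is which transcripts differ in the ganglia of dt27J animals at that stage. Total RNA of 3 wild-type (WT) and 3 dt27J animals of the C57BL/6 background, from 2 litters, was hybridised to 1 single-colour array each. The labels carry 2 dates, which coincide with 2 slides. WT 1, WT 2, dt27J 1 and dt27J 2 belong to the first date, and WT 3 and dt27J 3 to the second. Whether a date is a litter is not stated in the sources used here.

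Between 63.1% and 71.5% of the 41174 non-control probes were well above background on an array, and the repeated spots of a probe varied by an SD of 0.13 to 0.20 on the log2 scale. The number of arrays, 3 per genotype, limits the precision. WT 1 and WT 2 differed from each other by an SD of 0.38 over the tested probes, and dt27J 1 and dt27J 2 by 0.48. WT 3 differed from WT 1 and WT 2 by 0.62 and 0.61, and dt27J 3 differed from dt27J 1 and dt27J 2 by 0.87 and 0.90. The first principal component carried 47.6% of the variance and placed dt27J 1 and dt27J 2 at 84.8 and 68.9, dt27J 3 at -10.4 and the WT arrays between -58.7 and -40.6. Xist and the Y-linked probes gave 2 males and 1 female among the WT animals and 1 male and 2 females among the dt27J animals.

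Dst itself was lower in dt27J ganglia on all 3 of its probes. The brightest probe fell by 2.68 on the log2 scale (SE 0.26, n = 3 arrays per genotype), a 6.42-fold decrease with a 95% interval of 4.19 to 9.83, to 15.6% of the WT signal (adjusted p = 0.0341, limma). The other probes fell by 2.42 (SE 0.27, adjusted p = 0.0376) and by 2.46 (SE 0.40, adjusted p = 0.0454), to 18.7% and 18.2% of WT, and each was well above background on 2 of the 3 dt27J arrays. With the authors' values these dimmer probes stood at -1.38 and -1.31 (adjusted p = 0.0386 and 0.0387). Every dt27J array lay below every WT array on each probe. Within the first date the fold changes were -3.00, -2.77 and -2.91, and within the second date, with 1 array per genotype, -2.05, -1.71 and -1.56. Which part of the gene the allele alters is not given in the sources used here, so how far these probes check the labels is open. The adjusted p lay above 0.05 on the dimmer probes without the date block (0.0515 and 0.0586) and after another background correction (0.0843 and 0.129), and on all 3 probes without a filter on dim probes (0.0933 to 0.0988). That background correction was distorted by a few high local backgrounds. With these replaced, a step chosen after the data were seen, all 3 probes passed (0.0108 to 0.0432). The threshold was also missed on all 3 probes without WT 1 (0.248 on each), without WT 2 (0.150 to 0.159) or without dt27J 1 (0.168 to 0.171), and on 1 probe without dt27J 2 (0.0739).

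**Figure D1:**
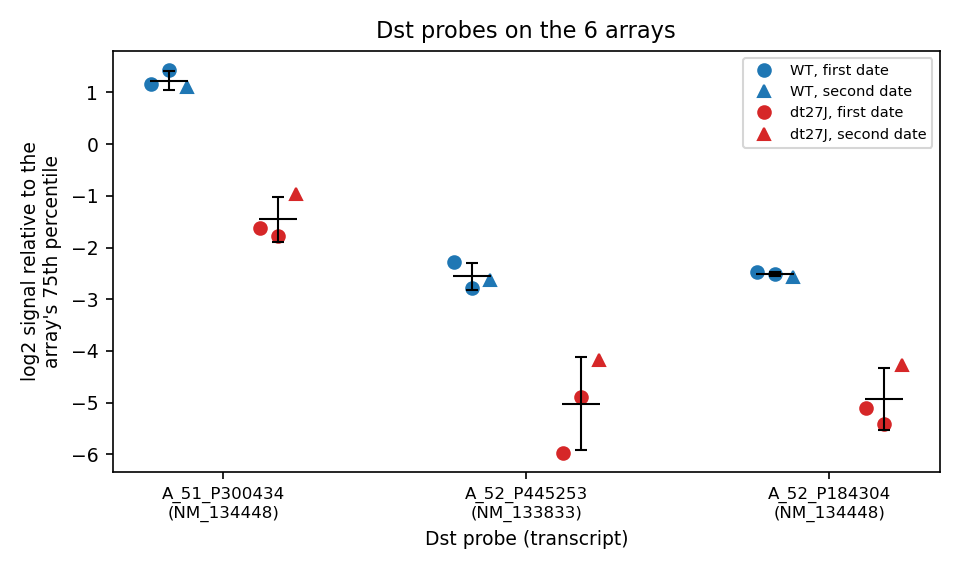
The log2 signal relative to the array's 75th percentile (vertical axis) is plotted for the 3 Dst probes (horizontal axis) on each of the 6 arrays, with WT in blue and dt27J in red, circles for the first date, triangles for the second, and lines for the mean ± SD of 3 arrays. On the brightest probe the WT mean was 1.23 and the dt27J mean -1.45, and the dt27J array of the second date lay nearest to WT on each probe.

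Across the genome, the largest falls in dt27J ganglia were in Lars2, the mitochondrial leucyl-tRNA synthetase, in Syt10, a synaptotagmin, and in Prm1, a sperm protamine. Lars2 fell by 4.88 on the log2 scale (SE 0.63, 29.5-fold, adjusted p = 0.0413), from a WT mean of 9.72 above the 75th percentile. Syt10 fell by 4.46 (SE 0.69), Prm1 by 3.99 (SE 0.64) and Cdk5r2, an activator of the neuronal kinase Cdk5, by 3.93 (SE 0.55). A second Prm1 probe stood at -0.32. The largest rise was on 1 of 3 tested probes of Zfp945, a zinc finger protein. That probe was well above background on no WT array and on all 3 dt27J arrays. By the main values it was at least 76.8-fold higher (adjusted p = 0.0153). The other Zfp945 probes stood at -0.95 and -1.22, with WT means of 0.66 and -1.84. Genes of striated muscle and the secreted hormone Fgf21 (2.81, SE 0.42) were also among the largest rises.

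In all, 838 of 26248 tested probes passed an adjusted p of 0.05, with 344 higher and 494 lower in dt27J, and 7270 probes had an unadjusted p under 0.05. The balance turned with the processing: 537 were higher and 440 lower after quantile normalization, 614 and 561 with the authors' values and 261 and 97 after normexp. With a few high local backgrounds replaced, a step chosen after the data were seen, normexp gave 1449 probes, 625 higher and 824 lower. The 838 probes stood for 564 gene symbols, and 226 of them had no symbol. The median change was 2.49-fold among the higher probes and 2.78-fold among the lower ones. All 838 had the same sign within both dates, as the choice of probes with a small error favours; the fold changes of the 2 dates correlated across these probes at r = 0.91 and across all tested probes at r = 0.20, and genes are not independent replicates. Their adjusted p values lay close to the threshold, with a median of 0.0472 and a smallest value of 0.00566, and 14 probes passed without the date block, 0 without a filter on dim probes, 358 after another background correction and 12199 with array weights. Without WT 1 the count was 1, and without WT 2 or without dt27J 1 it was 0. It was 168 without dt27J 2 and 6805 without either array of the second date. At an unadjusted p under 0.05 these counts of 0 stood beside 8485 probes without the filter, 4990 without WT 2 and 4475 without dt27J 1.

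The 12 largest rises included 4 genes of striated muscle. They were Mb, which encodes the oxygen carrier myoglobin (3.26, SE 0.55), Ckmt2, a mitochondrial creatine kinase (2.88, SE 0.43), Tcap, a protein of the Z disc (2.43, SE 0.31), and Myh1, a fast myosin heavy chain (2.40, SE 0.41). The same genes were higher in WT 3 than in WT 1 and WT 2, by 2.56, 2.05, 1.20 and 0.74. The other rises were Wfdc18 (3.39, SE 0.61), the glutathione transferase Gsta2, which was not well above background on any WT array and was at least 4.79-fold higher, the serine protease Corin (2.71, SE 0.37), Unc93a (2.61, SE 0.35), the steroid dehydrogenase Akr1c18 (2.45, SE 0.42) and the homeobox gene Meox2 (2.42, SE 0.44). These rises had adjusted p values between 0.0413 and 0.0472. A second Wfdc18 probe stood at 3.45 and a second Meox2 probe at 1.32. Other probes of the same symbol stood apart for Zfp945 (-0.95 and -1.22) and Myh1 (-0.17).

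The other falls among the 12 largest included the milk protein Lalba (-3.37, SE 0.55). Fam110a (-3.71, SE 0.63), Rusc1 (-3.36, SE 0.45), Ttll10 (-3.30, SE 0.56), Zc3h12d (-3.12, SE 0.34) and Ppp1r13l (-3.09, SE 0.36) fell as well. Gpr17, a receptor of the oligodendrocyte lineage, fell by 3.70 (SE 0.61), and WT 3 stood at -3.48 relative to WT 1 and WT 2. Irs4 stood at -1.60 there, and on the other 10 of these falls WT 3 lay above WT 1 and WT 2, from 0.56 for Rusc1 to 3.26 for Syt10. Irs4 was well above background on all 3 WT arrays and on no dt27J array, and was at least 2.11-fold lower (adjusted p = 0.0296). The places of Irs4, Gsta2 and Zfp945 among the 12 rest on signals that were not well above background in 1 genotype. Fgf21 and Akr1c18 were well above background on 1 of 3 WT arrays, and Ttll10 and Zc3h12d on 1 of 3 dt27J arrays. After normexp background correction these stood at 0.44, 0.24, -0.69 and -0.36, Lalba at -0.52, Irs4 at -0.34, Gsta2 at 0.64 and Zfp945 at 2.64, so the folds and bounds of dim probes depend on the background handling. After it 10 of the 24 genes passed, and 18 with a few high local backgrounds replaced, a step chosen after the data were seen. On all 6 arrays, 14 of the 24 genes were well above background. Second probes stood at -0.32 for Prm1, -0.70 for Rusc1, -0.68 for Ppp1r13l and -1.27 for Irs4. All 24 of these named genes lay on the same side of WT in both dates, as the rule that named them requires.

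**Figure D2:**
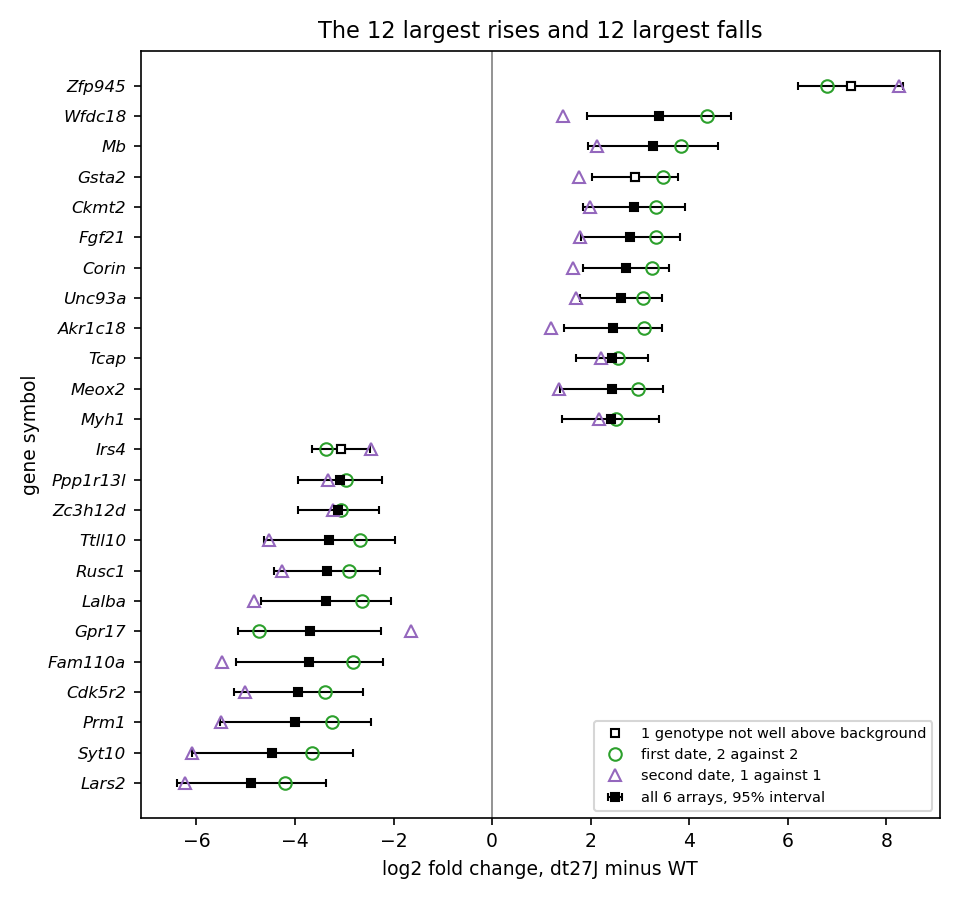
The log2 fold change of dt27J over WT (horizontal axis) is plotted for the 12 largest rises and 12 largest falls (vertical axis), as squares with 95% intervals over 6 arrays, circles for the first date (2 arrays against 2) and triangles for the second (1 against 1). Open squares mark Zfp945, Gsta2 and Irs4, whose values rest on a genotype that was not well above background. Mb stood at 3.26 and Lars2 at -4.88, and both symbols of every gene lay on the same side of 0, as the naming rule requires.

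Sensory neuron transcripts were lower in dt27J ganglia, by list tests that passed at a preset correlation between genes and not at an estimated one. Of 23 measured voltage-gated sodium and potassium channel genes, which set neuronal excitability, 22 had a negative fold change, with a median of -0.84. Kcnc1 (-1.18, SE 0.21) and Scn11a (-1.20, SE 0.23) were among those that fell over all probes, and 14 channel genes fell when adjusted over the list alone. Of 19 pan-neuronal and sensory neuron genes, 18 had a negative fold change (median -0.58), and the sensory neuron transcription factor Tlx3 fell by 2.40 (SE 0.46), with 8 falls when adjusted over the list alone. Nociceptor markers were lower too. The 8 peptidergic markers had a median of -0.31, with 2 falls adjusted over the list alone, and Scn11a fell among 12 non-peptidergic markers (median -0.62, 3 falls adjusted over the list alone). The proprioceptor list did not pass, with a median of -0.059 over 10 genes (adjusted p = 0.995) and of 0.099 and -0.27 within the 2 dates. Low-threshold mechanoreceptor markers went both ways (median -0.54, adjusted p = 0.233), since the calcium-binding protein gene Necab2 fell by 1.54 (SE 0.22) and the transcription factor Maf rose by 1.08 (SE 0.20), with 3 lower and 1 higher when adjusted over the list alone. Other probes stood at -0.24 and -1.79 for Kcnc1 and at 0.51 for Maf.

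Genes of microtubules and motors were lower as well at the preset correlation, though not at an estimated one (adjusted p = 0.437), and few single genes passed for calcium handling or cholesterol synthesis. Of 31 microtubule and motor genes, 28 had a negative fold change (median -0.53), Tubb4a, a beta-tubulin, fell by 1.12 (SE 0.20), and 6 fell when adjusted over the list alone. The dynactin subunit Dctn1 stood at -1.46 (adjusted p = 0.0519). The 24 calcium handling genes had a median of -0.38, with 0 past the threshold over all probes and 1 lower when adjusted over the list alone, which was the T-type channel gene Cacna1h (-1.35), and a second-date median of -0.086. The 22 cholesterol synthesis genes had a median of -0.44, with 0 past the threshold over all probes or over the list alone and Mvk at -1.14 (adjusted p = 0.0662).

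The tests of these lists gave adjusted p values, with camera at a preset correlation, of 3.78e-07 for the channels, 0.000109 for the pan-neuronal genes, 0.0325 for the peptidergic and 0.0105 for the non-peptidergic markers, 7.15e-05 for microtubules and motors, 0.0325 for calcium handling and 0.00451 for cholesterol synthesis. With an estimated correlation the adjusted p was 0.437 for each of these lists other than the non-peptidergic markers, where it was 0.543. Over all 33 lists tested, 16 passed at the preset correlation, 8 higher and 8 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.437; fry, which asks whether the genes of a list move on balance in 1 direction and does not set them against other genes, passed 7, with a smallest adjusted p of 0.0360. Those 7 were the channels, microtubules and motors, cholesterol synthesis, peptidergic nociceptors, low-threshold mechanoreceptors, immediate early genes and the endoplasmic reticulum (ER) chaperones. Within the first date, where the spinal cord list stood at -4.09 and the skeletal muscle list at 2.14, the medians were -1.11 for the channels, -0.78 for the pan-neuronal genes, -0.44 for the peptidergic and -0.78 for the non-peptidergic markers, -0.58 for microtubules and motors, -0.50 for calcium handling and -0.40 for cholesterol synthesis. Within the second date, where those tissue lists stood at 0.023 and 0.20, they were -0.60, -0.51, -0.39, 0.087, -0.43, -0.086 and -0.42. Leaving out WT 1 and WT 2, an alternative chosen after the data were seen, compares only WT 3 with dt27J 3 and so repeats these second-date medians. The pan-neuronal genes stood at 0.062 in WT 3, and at 0.023 and -0.0034 in WT 1 and WT 2, relative to the WT mean.

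**Figure D3:**
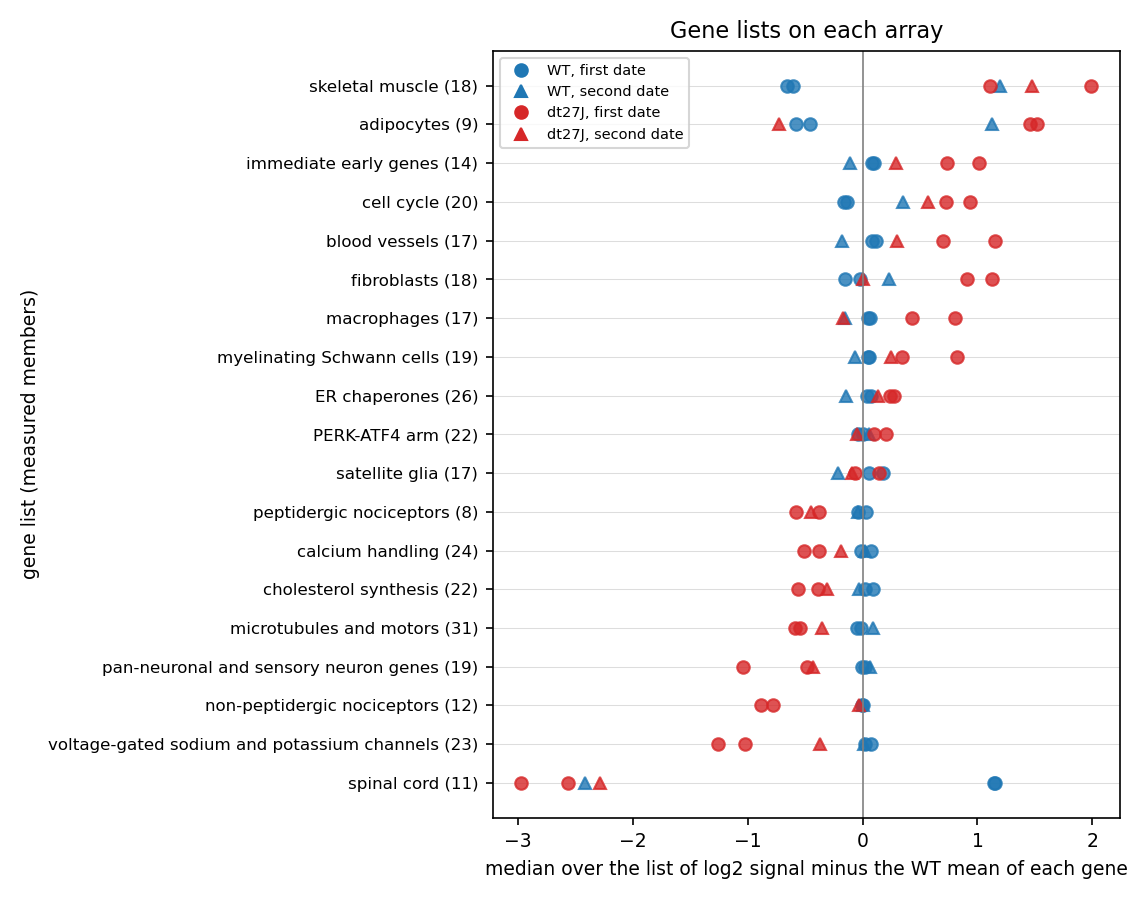
The median over each gene list of the log2 signal minus the gene's WT mean (horizontal axis) is plotted per array for 19 lists (vertical axis, measured members in brackets), with WT in blue, dt27J in red, circles for the first date and triangles for the second. The channel list stood at -1.26 and -1.02 on the first-date dt27J arrays and at -0.37 on dt27J 3, and the spinal cord list stood at 1.14 and 1.15 on WT 1 and WT 2 and at -2.41 on WT 3.

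Blood vessel and proliferation transcripts, and some glial genes, were higher in dt27J ganglia, by list tests that passed at the preset correlation and not at an estimated one (adjusted p = 0.437 for vessels and the cell cycle). Of 17 vessel genes, 16 had a positive fold change (median 0.73), the endothelial receptor gene Tek rose by 1.63 (SE 0.29), and 8 rose when adjusted over the list alone. All 20 cell cycle genes had a positive fold change (median 0.74), Top2a, a topoisomerase of dividing cells, rose by 1.17 (SE 0.19), and 9 rose when adjusted over the list alone. Among 19 genes of myelinating Schwann cells, Egr2, the transcription factor that drives myelination, rose by 2.00 (SE 0.31), Gldn by 1.69 (SE 0.24) and Bcas1 by 1.55 (SE 0.29), with 8 higher and 1 lower when adjusted over the list alone, a median of 0.41 and 10 positive and 9 negative fold changes. Among 17 markers of satellite glia and the Schwann lineage, Ednrb rose by 1.32 (SE 0.21) and Cdh19 by 1.85 (SE 0.36, well above background on 1 of 3 WT arrays), with 3 higher and 1 lower when adjusted over the list alone, but the list as a whole did not pass (7 positive and 10 negative fold changes, median -0.012, mean 0.12, adjusted p = 0.666). Of 17 macrophage genes, Aif1 rose by 1.01 (SE 0.19), the only one to pass over all probes or over the list alone, and the median was 0.44. The 18 genes of fibroblasts, meninges and extracellular matrix had a median of 0.69 with 0 past the threshold over all probes or over the list alone, and Postn at 1.28 (adjusted p = 0.0573).

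At the preset correlation the adjusted p was 9.12e-06 for vessels, 1.46e-06 for the cell cycle, 0.0489 for myelinating Schwann cells, 0.0105 for macrophages and 0.00154 for fibroblasts. With an estimated correlation the adjusted p was 0.437 for vessels and for the cell cycle, 0.443 for myelinating Schwann cells and macrophages and 0.543 for fibroblasts. Within the first date, beside the spinal cord list at -4.09 and the muscle list at 2.14, the medians were -0.021 for satellite glia, 0.90 for vessels, 1.02 for the cell cycle, 0.68 for myelinating Schwann cells, 0.68 for macrophages and 1.09 for fibroblasts. Within the second date, beside those lists at 0.023 and 0.20, they were 0.37, 0.45, 0.23, 0.34, 0.075 and -0.31. The cell cycle list stood at -0.16 and -0.14 on WT 1 and WT 2 and 0.35 on WT 3, relative to the WT mean. A second probe stood at 0.079 for Top2a and 0.32 for Ednrb, and a second Aif1 probe rose by 1.39 (SE 0.25).

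Transcripts induced by activity or stress rose in part. Among 14 immediate early genes (median 0.78), Fos rose by 1.64 (SE 0.22), Egr1 by 1.21 (SE 0.19) and the RNA-binding protein gene Zfp36 by 1.02 (SE 0.19), and 7 were higher and 2 lower when adjusted over the list alone. Klf2, chosen after its values were seen, stood at -3.29 (adjusted p = 0.0519), and a second Klf2 probe at 0.59. Atf3, a transcription factor induced by nerve injury and by the integrated stress response, rose by 1.56 (SE 0.19, adjusted p = 0.0377), with fold changes of 1.56 and 1.57 within the 2 dates. It was the only member of the PERK-ATF4 arm of the unfolded protein response to pass over all probes or over the list alone, out of 22, whose median was 0.11 (adjusted p = 0.0959). Ddit3, the pro-apoptotic factor of that arm, stood at 0.18 (adjusted p = 0.573), Atf4 at 0.19 and Psat1 at 0.77 (adjusted p = 0.0781). Of 26 ER chaperone and degradation genes, 21 had a positive fold change with a median of 0.21, and 0 passed over all probes or over the list alone. Xbp1 stood at 0.69 (adjusted p = 0.0820) and the chaperone Hspa5 at 0.23 (adjusted p = 0.503). The adjusted p at the preset correlation was 0.00298 for immediate early genes and 0.0325 for the ER list, and for both lists the adjusted p was 0.437 with an estimated correlation. Within the dates the medians were 0.77 and 0.32 for immediate early genes and 0.18 and 0.24 for the ER list, beside 2.14 and 0.20 for skeletal muscle.

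Genes related to dystonin by family or by partner did not move as a group. Among 16 measured plakins, spectrins and adhesion partners (median -0.20, adjusted p = 0.995), Erbin, a scaffold of junctions and receptors, rose by 1.08 (SE 0.19), with 3 higher and 3 lower when adjusted over the list alone. Itga6 stood at 1.03 (adjusted p = 0.0582) and Plec at -0.71 (adjusted p = 0.196). Among 13 intermediate filament genes (median -0.075, adjusted p = 0.936), 0 passed over all probes, and peripherin, Prph, stood at -1.45 (adjusted p = 0.0593) and was the only member to pass over the list alone. The neurofilament genes Nefl, Nefm and Nefh stood at -0.22, -0.45 and -0.59, with adjusted p values between 0.230 and 0.559. Gfap, which the spinal cord also uses, stood at -4.40 within the first date and 0.023 within the second.

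Markers of neighbouring tissues differed between the genotypes on the first date. The spinal cord list of 11 measured genes had a median of -2.49 (adjusted p = 8.10e-05; adjusted p = 0.443 with an estimated correlation), with 0 past the threshold over all probes and 9 lower when adjusted over the list alone. Aqp4, a water channel of astrocytes, stood at -5.56 within the first date and -0.090 within the second. The skeletal muscle list of 18 genes had a median of 1.57 (adjusted p = 7.47e-08; adjusted p = 0.443 with an estimated correlation). Tnnt3 rose by 1.84 (SE 0.28), Myog by 1.72 (SE 0.29) and Myh1 as above, and 14 rose when adjusted over the list alone. Tnnc2, its brightest member, stood at 1.66 (adjusted p = 0.0908). The muscle list stood at -0.60 and -0.66 on WT 1 and WT 2, 1.20 on WT 3 and 1.11, 1.99 and 1.47 on the dt27J arrays, relative to the WT mean.

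Of the remaining lists, none passed at the preset correlation. Adipocyte genes had a median of 0.94 (adjusted p = 0.103), with 2.20 within the first date, -1.22 within the second and Fabp4 at 1.15 (adjusted p = 0.308). Nerve injury and regeneration genes had a median of 0.26 (adjusted p = 0.168), with Atf3 past the threshold over all probes and 3 higher when adjusted over the list alone. The Hox genes, which mark axial level, had a median of -0.32 (adjusted p = 0.0842), with Hoxb9 at -1.06 (adjusted p = 0.0695). Cartilage and bone genes had a median of 0.079 (adjusted p = 0.935), where Cnmd fell by 1.05 (SE 0.20), Col2a1 stood at 1.08 (adjusted p = 0.0993), and 4 were higher and 3 lower when adjusted over the list alone. The median was 0.27 for erythroid cells (adjusted p = 0.120, Hba-a1 at 0.29), 0.16 for the interferon response (adjusted p = 0.282, 3 higher adjusted over the list alone), -0.10 for autophagy and lysosome (adjusted p = 0.354), 0.19 for apoptosis (adjusted p = 0.354, 4 higher and 1 lower adjusted over the list alone) and -0.20 for heat shock (adjusted p = 0.421). It was -0.12 for oxidative phosphorylation (adjusted p = 0.685) and -0.017 for Golgi, coat proteins and vesicle transport (adjusted p = 0.936). Camera's direction was up for the Golgi list, the satellite glia and the proprioceptors, whose medians were below 0. In these lists 0 genes passed over all probes other than those named, and the sex-linked list, with 5 genes on the array and 0 well above background on every array of a genotype, was not tested. Scn11a and Atf3 each count in 2 lists.

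The second date differed from the first, with genotype held constant, on 28 of 26248 probes, of which 26 were higher and 2 lower. The largest named differences, chosen after their values were seen, were Wdr95 (4.51, SE 0.24, adjusted p = 0.0119), Stra6, a retinol transporter (4.49, SE 0.41, adjusted p = 0.0312), and L3mbtl2 (4.07, SE 0.31, adjusted p = 0.0199), all higher on the second date, and Chrdl1, a bone morphogenetic protein antagonist, was lower (-2.19, SE 0.23). At an unadjusted p under 0.05 the count was 4015. It was 4509 without a filter on dim probes, 21516 after another background correction and 0 with array weights, and leaving out 1 array gave 0 (WT 1, dt27J 1 or dt27J 2), 1 (WT 2), 263 (dt27J 3) or 4272 (WT 3), where limma's counts of 0 stood beside 1828 to 2730 probes at an unadjusted p under 0.05.

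The genotype difference itself differed between the dates on several genes that noradrenergic neurons use. These genes, named after their values were seen, were high on WT 3, dt27J 1 and dt27J 2 and low on WT 1, WT 2 and dt27J 3. Dbh, which makes noradrenaline, was 4.47 higher in dt27J on the first date and stood at -5.97 on the second (adjusted p = 0.00101 for the difference), the neuropeptide gene Npy at 4.74 and -6.51 (adjusted p = 0.00255) and Th, the rate-limiting enzyme of catecholamine synthesis, at 2.58 and -2.51 (adjusted p = 0.0326). Slc6a2, the noradrenaline transporter, passed too (adjusted p = 0.00101) but was well above background on 1 of 3 WT arrays. A list of 10 other sympathetic neuron genes went both ways, with a median difference of -0.69. Adipocyte genes followed the same arrays, with Adipoq at 2.86 and -2.53 and 4 of 9 measured adipocyte genes past the threshold. Of 11 spinal cord genes 8 passed, with a median of -4.09 on the first date and 0.023 on the second. Those with the largest second-date values, chosen after they were seen, were Olig1, well above background on 2 of 3 dt27J arrays, at -6.46 and 2.03 and the inhibitory transporter gene Slc32a1 at -5.14 and 1.21.

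In total the limma interaction of genotype and date passed on 218 of 26248 probes, with 94 positive and 124 negative differences, and 7216 probes had an unadjusted p under 0.05. None of the 218 was among the 838 probes that passed for genotype, and on 188 the fold change had opposite signs in the 2 dates. WT 3 differed from WT 1 and WT 2 by at least 1 on the log2 scale on 158 of the 218 probes, and dt27J 3 differed from dt27J 1 and dt27J 2 by as much on 160, against 6.75% and 20.4% of all tested probes. The second date holds 1 animal per genotype, so the difference rests on single animals there. The count was 0 without WT 1 or without WT 2 (6239 and 4634 at an unadjusted p under 0.05), 2858 without dt27J 1 and 2740 without dt27J 2, and the other processing choices gave 405 to 2378 where they moved it by over 1.5 times, and 2687 with a background correction chosen after the data were seen.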

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

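The tests of a dt27J effect on spinal cord genes and on skeletal muscle genes and the test of sex were chosen only after the result was seen, and the tests on second lists of central nervous system, muscle and sympathetic genes before.

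The genotype difference differed between the 2 dates on 218 probes, by a test of that difference itself, among them noradrenergic, adipocyte and spinal cord genes. Sex as the only cause would leave animals of 1 sex alike. The adipocyte median stood 2.07 apart among the males and 1.957 among the females (95% interval 0.43 to 2.83, n = 9 genes). The animals were grouped along the pattern already seen, so the direction of these gaps was built in. Only their size speaks against sex alone. Within each sex 1 animal was set against 2, and the interval resamples genes, not animals. Dbh stood at -4.14 and -4.05 on the males WT 1 and WT 2 and 0.32 on the male dt27J 2, and at 0.89 and 0.44 on the females WT 3 and dt27J 1 and -5.08 on the female dt27J 3. Spinal cord tissue in WT 1 and WT 2, and more muscle tissue in the other 4 samples, may account for part: 15 other central nervous system genes were 1.30 higher in WT 1 and WT 2 (0.97 to 1.81, against 0.23 at the 95th percentile of random lists), though not Gpr37l1 (-0.14), Gjb6 (0.078) or Zic1 (-0.067), and 23 other muscle genes 1.81 higher in the other 4 samples (1.07 to 2.21, against 0.19). A dt27J effect cannot be told apart on these lists, because WT 3 alone speaks against it. WT 3 lay 0.36 above the dt27J mean for spinal cord genes (-0.41 to 0.69, n = 11), where WT 1 and WT 2 lay 4.01 above. For muscle genes it lay 0.16 below that mean (-0.060 to 0.62, n = 18), where they lay 2.24 below. Mb (2.13), Ckmt2 (1.99), Tcap (2.20) and Myh1 (2.18) were higher in dt27J on the second date too, but the rule that named them required this. The whole muscle list had a second-date median of 0.20. Sympathetic ganglion tissue in WT 3, dt27J 1 and dt27J 2 cannot be told apart from other sources of the noradrenergic difference, because 10 other sympathetic genes went both ways, with a median of -0.69 (-1.67 to 0.997, against -0.71 at the lower end of random lists), with Maoa at -2.10, Adra2c at 1.34 and Hand2, well above background on 1 of 3 WT arrays, lowest, and litter stays untested.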

How the results depend on the processing

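Normexp with the high local backgrounds replaced, sex as a term and leaving out WT 1 and WT 2 together were chosen only after the data were seen; the other alternatives were planned. The naming rule asks for the same sign within each date, so leaving out arrays could not reverse a named gene. The 24 named genes and 3 Dst probes kept their direction in every alternative run, but not their side of the threshold. In the alternatives fixed beforehand 208 of 374 values of the named genes and 26 of 46 of the Dst probes stayed past it, and in those added later 18 of 72 values of the named genes did. The planned tallies, also of lists and list members, count fits that are not separate tests. For genotype, leaving out WT 3 or dt27J 3 equals the first date alone, and leaving out saturated probes equals the main fit. The planned tallies also count the array weights, whose fit did not converge. Among the alternatives added later, leaving out WT 1 and WT 2 leaves only the second-date difference, with 1 animal per genotype. Of 320 planned values of the 16 lists, 272 stayed past it and 48 did not, with 0 reversals, and the list count was 12 to 17 when 1 array was left out. Of 2570 planned values of list members, 2135 kept their side, 186 lost it and 249 gained it. Signal over background limits 60 of the 838 probes, well above background on no array of 1 genotype, to a bound. No probe was saturated, so that alternative moved nothing. Where no reason is given, the cause was not tested.

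Of the Dst probes, those at -2.42 and -2.46 lay above 0.05 without the date block (adjusted p = 0.0515 and 0.0586), as did all 3, at -2.42, -2.68 and -2.46, without the filter on dim probes (0.0933 to 0.0988). After normexp the dimmer probes stood at -0.75 (adjusted p = 0.0843) and -0.64 (0.129). With the high local backgrounds replaced, normexp left all 3 probes past the threshold (adjusted p = 0.0108 to 0.0432). Leaving out 1 array gave -2.77 to -2.22, -3.00 to -2.51 and -2.91 to -2.02. Without WT 1 and WT 2 the probes stood at -1.71, -2.05 and -1.56, which are the second-date values of 1 array per genotype. With sex as a term, a fit equal to leaving out dt27J 1, they stood at -2.41, -2.63 and -2.02 (0.168 to 0.171).

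The replicate numbers did not pair the samples, with correlations of same-numbered deviations of 0.22, -0.15 and 0.062, and not every sample correlated best with its own number. With the number as a block in place of the date, 2 probes passed for genotype, and the Dst probes kept -2.42, -2.68 and -2.46 with adjusted p values of 0.0980 to 0.110. The block changed the list count from 16 to 16.

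The genotype count of 838 became 14 without the date block, 358 after normexp (145 shared with the 838), 0 without the filter, 12199 with array weights, whose fit did not converge and gave WT 1 a weight of 67.4, 1259 with 1 value per symbol and 6805 on the first date alone. The looser thresholds, by their construction, gave 4019 (adjusted p under 0.1) and 6336 (unadjusted p under 0.05 and 1.5-fold). Leaving out 1 array gave 0 to 6805, and the count was 0 with sex as a term, with 4475 at an unadjusted p under 0.05. The share of higher probes, 41.1%, became 55.0% after quantile normalization (977 probes, 746 shared), 52.3% with the authors' values (1175, 608 shared) and 72.9% after normexp, but 43.1% after normexp with the high local backgrounds replaced.

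Normexp was distorted by 47 spots on WT 3 and 6 on dt27J 3 with a local background over 100, where array medians were 19 to 22. It gave 21516 probes for the date, and with these backgrounds replaced by the array median 61, with 1449 for genotype (497 shared) and 2687 for the interaction. The date count of 28 was otherwise 17 after quantile normalization, 4509 without the filter, 48 with the filter on all 6 arrays, 0 with array weights and 0 to 4272 without 1 array. The interaction count of 218 was 1142 after normexp, 1623 with the authors' values, 405 without the filter, 995 with the filter on all 6 arrays, 2378 with a trended and robust prior and 0 to 2858 without 1 array of the first date.

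Of the lists, 0 passed with an estimated correlation and 7 with fry. Without WT 1 and WT 2 the list medians are those of the second date, with 1 animal per genotype. There the spinal cord median was 0.023, the fibroblast median -0.31 and the non-peptidergic nociceptor median 0.087, all of the opposite sign to the main fit.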

Other observations

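The tests on the neuronal and vessel lists, of sex and on the probes that fell like Lars2 were chosen only after the result was seen; the counts of splits and the test of the genes next to Dst were chosen before.

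Beyond the genes already named, the noradrenergic profile of high signal on WT 3, dt27J 1 and dt27J 2 was shared by the transcription factor Phox2a (4.88 within the first date, -5.94 within the second), the vesicle transporter Slc18a2 (5.69 and -5.06) and the decarboxylase gene Ddc (4.25 and -4.47). The adipocyte genes Plin1 (2.20 and -3.08) and Cidec (2.46 and -1.92) followed the same arrays. These probes passed the interaction test and were chosen after their values were seen. A second Slc18a2 probe stood at 4.46 and -3.74.

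Neuronal genes were lower and vessel genes higher in dt27J ganglia at a preset correlation between genes, but neither list passed at an estimated correlation (adjusted p = 0.437 for both) or with fry (0.0512 for both). Within sexes the neuronal median was -0.580 (95% interval -1.02 to -0.38, n = 19 genes), at -0.53 in males and -0.76 in females. The vessel median was 0.702 (0.497 to 1.102, n = 17 genes), at 0.65 and 0.76. Both kept their direction in each sex, but sex as the only cause stays open. Each sex holds only 1 animal of 1 of the genotypes, and the intervals resample genes, not animals. A lower share of neurons with nothing else changed cannot be told apart: it would raise the other cell types alike, and the vessel median exceeded the satellite glia median by 0.739 over all arrays (0.33 to 1.19, n = 34 genes) and by 0.92 on the first date (0.37 to 1.43), but by 0.079 on the second (-0.47 to 0.99). Neurons of spinal cord tissue in WT 1 and WT 2 cannot be told apart either, since the neuronal list stood at -0.092 in them relative to WT 3 alone (-0.23 to 0.16, n = 19 genes), where its shift between genotypes was 0.58. A hypothesis that stays open is that channel and sensory neuron transcripts may be reduced in dt27J ganglia before the phenotype. The dissection also stays open. Without WT 1 and WT 2, which leaves the second-date difference of 1 animal per genotype, the channel median was -0.60 and the vessel median 0.45.

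Lars2, Prm1 and Lalba were among the largest falls, and what the probes that fell have in common was examined. Spinal cord tissue in WT 1 and WT 2 cannot be told apart: WT 3 lay at least 1 below WT 1 and WT 2 on 29 of 494 of them, or 5.87% (exact 95% interval 3.97 to 8.32), against 3.01% of all tested probes, but a fit with a date term picks few probes of such a profile, and on Lars2, Prm1 and Lalba WT 3 lay above WT 1 and WT 2, by 0.63, 2.47 and 2.10. A single signal shared with Lars2 that differs in amount between samples cannot be told apart either. Over the probes that fell, the median correlation of deviations from the genotype means with those of Lars2 was 0.0934. That value is across probes and not independent samples, and lay below 0.152 at the 95th percentile of random sets. But the fit picks probes with a small error within dates, where Lars2 itself differed (4.25 on dt27J 1, 6.35 on dt27J 2). The random sets were not so picked. Of the probes that fell, 14 (2.84%) exceeded 0.9, against 1.39% of all tested probes. Among them were Ttll10 (0.987) and Rusc1 (0.947), and 9 of the other 11 named falls were positive. A positive correlation was not particular to the named falls. All of the 12 named rises other than Zfp945 (-0.48) were positive too, up to 0.857 for Corin. A dt27J effect on these transcripts and cross-hybridisation of single probes stay open and were not tested.

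With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 838 probes and the highest of the others 15, so 1 of 10 gave as many. For the gene lists 3 of 10 splits gave as many as the real 16. The highest other value was also 16, from the splits that put WT 1 and WT 2 with dt27J 2 or with dt27J 3.

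Strain DNA carried along with the mutant allele could change genes near Dst. Among the 164 measured genes nearest to Dst in the RefSeq table of GRCm38.p6, 8 passed (4.88%), against 4.11% of the other genes, an odds ratio of 1.197 (95% interval 0.51 to 2.43, Fisher's exact test, 2-sided p = 0.553), which leaves the explanation open. The 20 measured genes nearest to Zfp945 held 0 past the threshold in limma, with adjusted p values from 0.0573 to 0.934 and 6 at an unadjusted p under 0.05.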
